A study of Mus musculus with 2 samples.

How the data were processed

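Gene expression was measured on 2 Affymetrix Mouse Genome 430 2.0 arrays, 1 hybridised with RNA of untreated thioglycolate-elicited peritoneal macrophages and 1 with RNA of such cells after 12 h of 100 ng/ml CSF1. The groups were taken from the labels. The deposited values are intensity values on a linear scale, produced by the authors with GeneSpring 6.2 per the series' design text, and the mean after trimming 2% from each end was equal on both arrays. The summarization method is not given in the sources used here, and no detection calls were used here.

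The table held 45101 probe sets, of which 34958 carried 1 gene symbol, 932 several and 9211 none, the last including 64 Affymetrix control probe sets. Gene symbols were checked by Entrez ID against a RefSeq gene table, in which 204 of the probe sets with 1 symbol had no match and 0 symbols differed. Values were moved to the log2 scale without further scaling. Each of 18194 genes was represented by its probe set with the highest mean log2 level, among probe sets with exactly 1 symbol. A background level of 139.26 units was set at the 90th percentile of 128 probe sets of 82 genes of unrelated tissues, out of 90 fixed, and lower values were raised to it. Npy, among these genes, was far above this level on both arrays, so they were not all unexpressed. A gene counted as measured when at least 1 array was above this level, which held for 11039 genes, with 9654 above it on both arrays, 776 on the control array only and 609 on the CSF1 array only. For a gene at the background level on 1 array, the fold is given as a lower bound.

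The measure was the log2 ratio of the CSF1 array over the control array. With 1 array per group, no test, p-value or standard error was computed, and the number of arrays limits the precision. The spread given beside a gene is the SD between its probe sets above background on both arrays. Fixed beforehand were 32 gene lists and 13 marker lists of cell types. Each list with at least 3 measured members was given its median, with genes at background on 1 array entered at their bound, and the percentile of that median among 10000 random lists of the same size, matched in 20 bins of mean level. Named genes were the 12 highest and 12 lowest ratios among genes above background on both arrays whose other measured probe sets had the same sign, the 5 largest bounds per direction, up to 4 members of each list with the largest absolute ratio, with further members where they were within 2-fold or where a count of 5 or fewer was spelled out, and Csf1r, Csf1, Il34, Ccnd1, Myc, Actb and Gapdh. Probe sets with names ending in _s_at, _x_at or _a_at can match several transcripts. Among the genes named in the text, those of Gins2, Mcm2, Mcm7, Myc, Csf1, Socs2, Socs3, Dbp, Gzma, Prf1, Pim3, Tcea2, Sh3tc1, Dennd6b, Ackr3, Ier3, Il1b, Mx1, Lss, Srebf1, Slc2a1, Slc2a3, Pdk1, Hif1a, Vegfb, Vegfc, Birc3, Tfe3, Jdp2, Phgdh, Psat1, B2m, Psap, S100a8, Pdgfrb, Col1a2, Col3a1, Il34 and the immunoglobulin kappa segment are of this kind.

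The procedure was tested on a simulated pair of arrays with 10479 measured genes. Changes were placed only in genes well above the background level, and alike in all probe sets of a gene. Recovery of changes near that level was therefore not tested. All 100 genes changed 4-fold and 93 of 100 genes changed by 1.5 on the log2 scale were past 2-fold, as were 5 unchanged genes. Of 200 random lists of 20 genes, 8 lay outside the central 95%. The simulated log2 ratios had an SD of 0.29. The measured ones had an SD of 0.37 over probe sets above background on both arrays, and of 0.45 at the lowest mean levels. These counts therefore hold for the simulated noise only and give no error rate for the 2 arrays. The alternatives were quantile normalization, centring on the median of measured probe sets, a loess correction (span 0.3), centring on the hybridisation spikes, the background level at the median of all values or the 95th percentile of background genes or left out, the mean of all probe sets of a gene, probe sets not marked as shared, fold thresholds of 1.5 and 3, random lists not matched on level, and, added later, only genes above background on both arrays. For the mean of all probe sets, values were raised to the background level only after averaging, so probe sets below it entered the mean. Probe sets without a single gene name were left out of gene counts. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.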

Results

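Thioglycolate-elicited peritoneal macrophages are inflammatory macrophages that an irritant medium draws into the peritoneal cavity of mice, from which they are recovered by lavage. Cells from 8-week-old male C57BL6 mice were grown in culture to 80% confluence and then kept for 12 h without addition or with 100 ng/ml CSF1. CSF1 (macrophage colony-stimulating factor, M-CSF) is the growth factor that binds the receptor tyrosine kinase Csf1r and sustains the survival and proliferation of macrophages. RNA of 1 control sample and 1 CSF1 sample was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, and the comparison asks how gene expression differed between these samples after 12 h of CSF1. With 1 array per group, no difference given here has a replicate check, no test between the groups can be run, and the number of arrays limits the precision. The error given beside a gene is the disagreement between its probe sets, which had a pooled SD of 0.29 on the log2 scale over 3806 genes and covers neither cultures nor animals. The labels do not say whether both samples came from the same animals.

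Each array held 45101 probe sets, with a median signal of 101 units on the control array and 91.6 units on the CSF1 array. A background level of 139.26 units, taken from genes of other tissues, was exceeded by 42.5% of probe sets on the control array and 40.8% on the CSF1 array. Across the 17022 probe sets above it on both arrays, log2 signals had a Pearson r of 0.978 and a Spearman rho of 0.966, where probe sets are not independent replicates. The 18 hybridisation spike probe sets had a mean log2 ratio of CSF1 over control of -0.29 ± 0.13 (SD between spike probe sets), while the median over all 11039 measured genes was 0.00 under the authors' scaling. The ratio of 3' to 5' signal was 1.35 on the control array and 1.38 on the CSF1 array for Actb, and 1.03 and 1.40 for Gapdh, so this sign of RNA integrity differed between the arrays for Gapdh.

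Of the 11039 measured genes, 105 were at least 2-fold higher on the CSF1 array and 79 at least 2-fold lower. Of the 9654 genes above background on both arrays, 98.6% lay within 2-fold. Another 1337 genes, at background on 1 array, had a lower bound under 2-fold, which leaves their fold open. The higher genes comprised 76 measured on both arrays and 29 at the background level on the control array, for which the fold is a lower bound, and the lower genes comprised 60 and 19. With the arrays centred on the hybridisation spikes, the counts became 341 higher and 21 lower, because the median of all genes then stood at 0.28; relative to that median, 93 genes were higher and 93 lower.

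The largest ratio belonged to the monocyte-attracting chemokine Ccl12, whose signal was 405 units on the control array and 2642 units on the CSF1 array, 6.52-fold higher. Igfbp3, an insulin-like growth factor binding protein, was 4.99-fold higher, and its 2 probe sets had a mean log2 ratio of 2.35 ± 0.04 (SD between probe sets). The extracellular matrix gene Efemp1 was 3.51-fold higher, and Mgp, which encodes matrix Gla protein, an inhibitor of calcification, was 2.87-fold higher. Gins2, a subunit of the replicative helicase complex, was 2.99-fold higher on a probe set whose name marks it as possibly shared with other transcripts, and 2.15-fold higher on its other probe set. The kinase gene Pak4 was 3.35-fold higher, Scel (sciellin, an epithelial protein) 3.16-fold, Cdpf1 3.06-fold and Rasl11a 2.92-fold. An immunoglobulin kappa variable segment was 3.14-fold higher on a probe set that can cross-hybridise with related segments. Dnaaf2 and Desi1 were 3.32-fold and 2.91-fold higher on their brightest probe set and 1.005-fold and 1.21-fold on their other one. On the control array Pak4, Cdpf1, Rasl11a, Dnaaf2 and the immunoglobulin segment lay between 144.1 and 179.2 units. This is under the 95th percentile of background genes, 184.42 units, and with that level their folds are lower bounds. The largest lower bounds among genes at background on the control array were those of Trmt61a, a tRNA methyltransferase subunit, at least 3.80-fold higher, Dennd6b, at least 2.94-fold, Adarb1, an RNA-editing enzyme, at least 2.88-fold, the interleukin-17 receptor gene Il17re, at least 2.68-fold, and Dact3, at least 2.502-fold. Another probe set of Adarb1, measured on both arrays, had a log2 ratio of 0.10.

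Among the lowest ratios, the calcium channel subunit gene Cacng7 was 3.80-fold lower on the CSF1 array, with 693 units on the control array and 182 units on the CSF1 array. Granzyme genes followed, with Gzma 3.29-fold lower and Gzmb 2.76-fold lower; granzymes are the proteases of cytotoxic lymphocyte granules. The arginase gene Arg2 was 3.14-fold lower, and its 2 probe sets had a mean log2 ratio of -1.26 ± 0.56 (SD between probe sets). Chil3 and Ccl24, a chitinase-like protein and an eosinophil-attracting chemokine that interleukin-4 induces in macrophages, were 2.85-fold and 2.76-fold lower. The clock gene Per2 was 2.74-fold lower, and the clock-controlled transcription factor genes Dbp and Nfil3 were 2.63-fold and 2.59-fold lower. Arrdc3, an arrestin-domain gene, was 2.60-fold lower, and the calcium-permeable channel gene Trpm2 was 2.59-fold lower. Zap70, a kinase of T-cell receptor signalling, was 3.06-fold lower on its brightest probe set and 1.002-fold lower on its other one. On the CSF1 array Per2, Trpm2, Zap70 and Cacng7 lay between 144.5 and 182.3 units. With the background level at the 95th percentile of background genes, 184.42 units, their folds are lower bounds. Genes at background on the CSF1 array with the largest bounds were Tcea2, at least 3.38-fold lower, the kinase gene Pim3, at least 3.13-fold, Sh3tc1, at least 2.93-fold, the neutrophil protease gene Prtn3, at least 2.80-fold, and Arid5a, at least 2.40-fold.

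Where a gene measured on both arrays and past 2-fold had another probe set above background on both, that probe set mostly pointed the same way but gave a smaller ratio. This held in direction for 15 of 20 higher genes, of which 4 were also past 2-fold, with a median log2 ratio of 0.40. Among lower genes, it held for 14 of 16, of which 5 were past 2-fold, with a median of -0.58. Averaging all probe sets of a gene kept 50 of the 105 higher and 41 of the 79 lower genes past 2-fold. It brought Dnaaf2 (0.87), Desi1 (0.82), Cacng7 (-0.84), Zap70 (-0.14), Trpm2 (-0.55), Il17re (0.02), Tcea2 (-0.28) and Pim3 (-0.59) under 2-fold on the log2 scale, and left Scel, the immunoglobulin segment, Per2, Dennd6b, Adarb1 and Dact3 below background. This average takes in probe sets below background, since values were raised to that level only after averaging. Cacng7, Trpm2, Uhrf1, Egln3, Cxcl9, Gas6, Cebpd and Zbtb46 are among the genes with only 1 probe set above background on both arrays. Their averages do not show disagreement between probe sets measured on both. Ccl12, Efemp1, Mgp, Gzma, Gzmb, Chil3, Ccl24, Per2, Tk1, Cdk1, Bnip3 and Csf3r also have only 1 such probe set, and so no SD between probe sets. Gene values under an alternative are relative to the median of all measured genes under it. With the background level at the 95th percentile of background genes, the bounds of Dact3 (0.91) and Arid5a (-0.86) came under 2-fold.

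**Figure D1:**
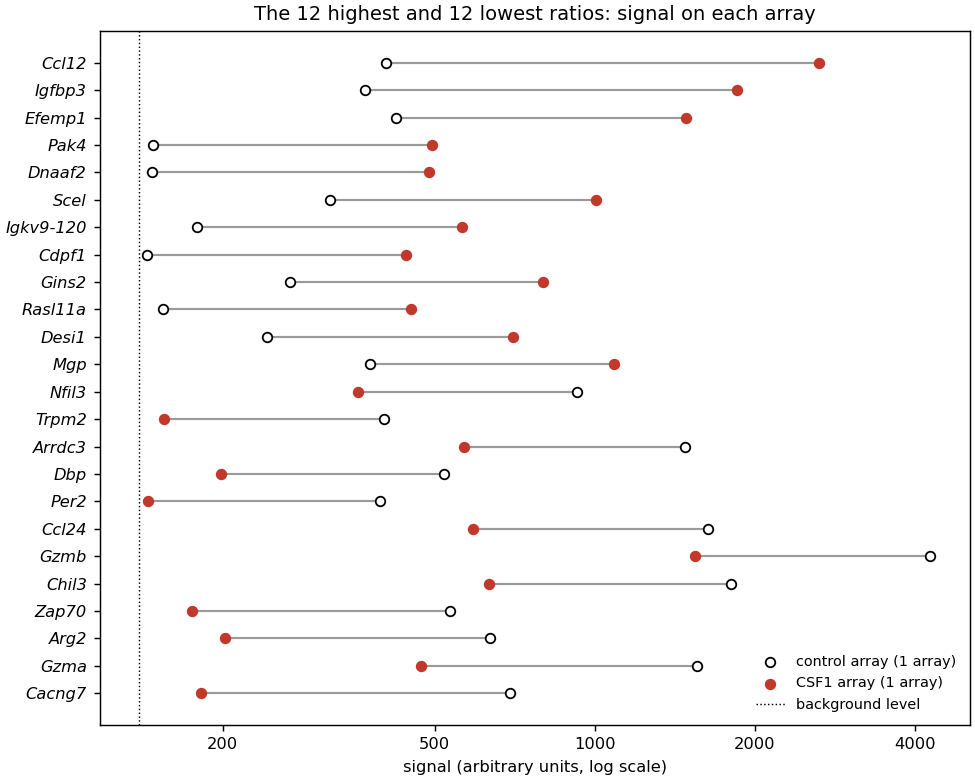
Signal in arbitrary units, on a log axis, on the control array (open circles) and the CSF1 array (filled circles) for the 12 genes with the highest and the 12 with the lowest ratio among those above background on both arrays, 1 array per group and hence no error bars. The dotted line is the background level of 139.26 units, and distances are to be read within a gene only, from 6.52-fold higher for Ccl12 to 3.80-fold lower for Cacng7.

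The gene lists fixed before the data were examined were summarised by the median log2 ratio of their measured members and by its percentile among 10000 random lists of the same size and level. This percentile describes these 2 arrays only. Of 43 lists with at least 3 measured members, 5 lay above and 9 below the central 95% of such random lists, where lists of independently drawn genes would give 2.1 in all. Members of a list can move together and some lists share genes, so 2.1 is not a chance rate for these lists. Of the 14, 10 stayed outside on the same side under all 10 processing alternatives that recompute a list. Centring on the median or the spikes shifts all genes alike, so apart from the background level it cannot move a list relative to other genes. Centring on the spikes put the median of all genes at 0.28, so higher and lower lists are so relative to other genes.

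DNA replication genes were higher as a group. Of 29 measured, 28 had a log2 ratio above 0, 8 were at least 2-fold higher and none was 2-fold lower, with a median of 0.67, or 1.59-fold (percentile 100.00). After Gins2, the highest were the helicase subunit gene Mcm2 at 2.52-fold, thymidine kinase Tk1 at 2.40-fold and Uhrf1, which maintains DNA methylation at the replication fork, at 2.29-fold. The other 4 past 2-fold were Gins1, Mcm7, Lig1 and Ccne2, and the exception below 0 was Pola1, at -0.27. On probe sets not marked as shared, Mcm2 was at 0.82 relative to the median of all measured genes. Averaging all probe sets of Uhrf1 brought it to 0.32. The G1 cyclin gene Ccnd1 was 2.07-fold higher, with a mean log2 ratio of 0.98 ± 0.23 (SD between 3 probe sets), and Myc was 1.32-fold higher. Genes of mitosis had a smaller median of 0.19 (26 measured, percentile 96.77, inside the random range), with 20 above 0 and 3 at least 2-fold higher. These were the mitotic kinase gene Cdk1 at 2.35-fold, the kinesin gene Kif23 at 2.25-fold and the ubiquitin-conjugating enzyme gene Ube2c at 2.13-fold, while the proliferation marker Mki67 had a log2 ratio of 0.14. Kif23, whose control signal was at the background level's edge, had a lower bound of 0.76 with the stricter background level and no value when all probe sets were averaged. The mitosis list lay above the random range under 5 of the 10 alternatives, up to percentile 99.28, and at 99.22 when random lists were not matched on level. Cyclin-dependent kinase inhibitors and growth arrest genes had a median of -0.17 (21 measured, percentile 1.28), with 15 below 0 and none past 2-fold. Within that list the CDK inhibitor gene Cdkn2c was 1.67-fold higher and the antiproliferative gene Btg2 1.65-fold lower (log2 ratio -0.03 on its other probe set). Its median was -0.06 on probe sets not marked as shared, at percentile 19.50.

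Hypoxia target genes were lower as a group. Of 21 measured, 20 had a log2 ratio below 0 and 3 were at least 2-fold lower, with a median of -0.43, or 1.35-fold lower (percentile 0.00). The mitophagy receptor gene Bnip3 was 2.42-fold lower, the oxygen-sensing prolyl hydroxylase gene Egln3 2.32-fold, and the angiogenic factor gene Vegfa 2.01-fold, with a mean log2 ratio of -1.23 ± 0.32 (SD between 2 probe sets). Pdk1, a kinase that inhibits pyruvate dehydrogenase, was 1.75-fold lower, and Hif1a itself was 1.67-fold lower. Averaging all probe sets brought Egln3 to -0.70. Glycolysis and glucose uptake genes had a median of -0.29 (16 measured, 14 below 0, percentile 0.00), and the 15 members above background on both arrays lay within 2-fold. The glucose transporter gene Slc2a3 was 1.77-fold lower, the lactate exporter gene Slc16a3 at least 1.76-fold lower, and the glycolytic regulator Pfkfb3 1.55-fold lower. Pdk1, Slc2a1 and Hk2 are members of both lists. Oxidative phosphorylation genes had a median of -0.05 as deposited and 0.02 after quantile normalization (25 measured, percentile 42.05), and all lay within 2-fold.

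**Figure D2:**
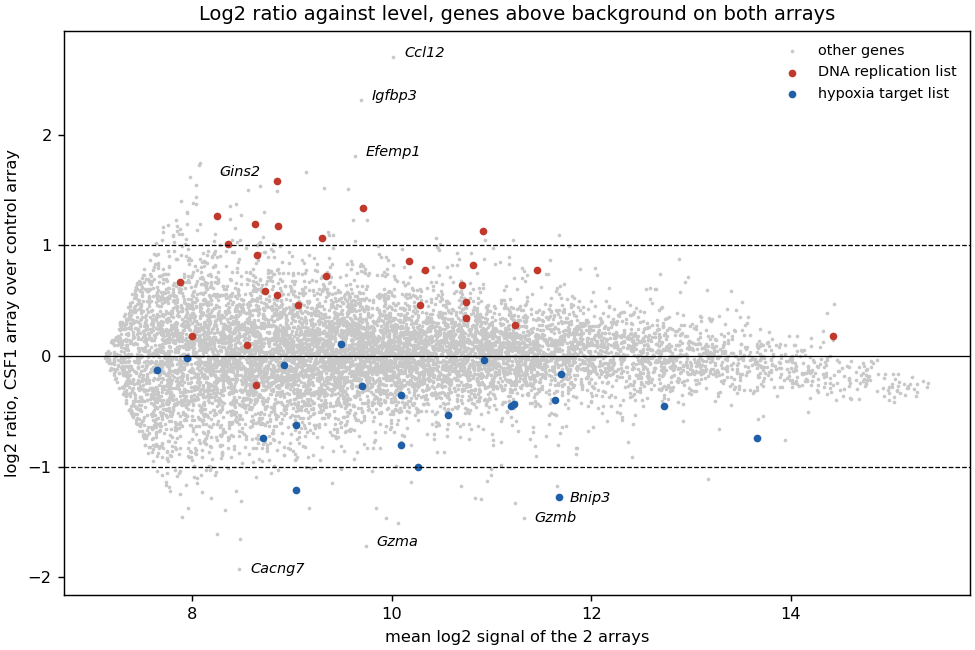
Log2 ratio of the CSF1 array over the control array against the mean log2 signal of the 2 arrays for the 9654 genes above background on both, 1 point per gene. Members of the DNA replication list (median 0.67) lie mostly above 0 and members of the hypoxia target list (median -0.43) mostly below 0, and dashed lines mark 2-fold.

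Genes of CSF1 and related cytokine signalling were mostly lower. General macrophage markers had a similar median of -0.27 (11 of 12 below 0), and a difference in the share of macrophages was not tested. In the list of the M-CSF receptor, its ligands and related cytokine receptors, 9 of 12 measured members were below 0, with a median of -0.35 (percentile 0.00). The cytokine-signalling inhibitor Socs3 was 2.20-fold lower, with a mean log2 ratio of -1.15 ± 0.12 (SD between 3 probe sets), and the G-CSF receptor gene Csf3r was 2.06-fold lower. Cish, another inhibitor of cytokine signalling, was 1.51-fold lower, and the shared receptor subunit gene Csf2rb 1.49-fold. The receptor gene Csf1r itself stood at 23704 units on the control array and 18697 units on the CSF1 array, 1.27-fold lower, with a mean log2 ratio of -0.36 ± 0.23 over 3 probe sets, and Csf1 was 1.34-fold lower, at -0.34 ± 0.18 over 4 probe sets. The other Csf1r ligand gene, Il34, was not above background on either array. The control genes Actb and Gapdh had mean log2 ratios of -0.30 ± 0.02 over 5 probe sets and -0.54 ± 0.22 over 3. On the brightest probe set of each, the ratio was -0.30 as deposited and -0.03 and -0.14 relative to the median after quantile normalization, so the size of these ratios depends on the scaling and, for Gapdh, on the probe set. Its 3', middle and 5' control probe sets were at -0.30, -0.57 and -0.74, which is the difference in 3' to 5' signal given above. Genes of the early mitogenic response and its feedback regulators had a median of 0.00 (23 measured, percentile 40.45), with 12 above 0 and 11 below, and of -0.26 (percentile 0.05) with no background level. Apart from Ccnd1, the most displaced were the immediate early gene Ier3 at 1.68-fold lower, the AP-1 subunit gene Fosl2 at 1.53-fold lower (log2 ratio 0.04 on its other probe set) and the receptor tyrosine kinase inhibitor Spry1 at 1.43-fold higher.

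Cholesterol synthesis and uptake genes were higher by small and similar amounts. Of 20 measured, 19 were above 0 and none was past 2-fold, with a median of 0.38, or 1.30-fold (percentile 100.00). Lanosterol synthase Lss was 1.78-fold higher, the sterol dehydrogenase gene Nsdhl 1.59-fold, squalene epoxidase Sqle 1.50-fold and Fdps 1.41-fold, and Ebp was the exception at -0.07. Fatty acid synthesis genes had a median of 0.05 (15 measured, percentile 65.44), with Srebf1, a transcription factor of lipid synthesis, 1.42-fold higher and the lipase gene Pnpla3 1.56-fold lower. Cholesterol efflux and LXR target genes had a median of -0.17 (13 measured, percentile 4.06), with the cholesterol exporter Abca1 1.45-fold lower, at -0.59 ± 0.08 over 3 probe sets, and the apolipoprotein gene Apoc1 at least 1.76-fold lower. Without genes at background on either array, that median was 0.00.

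Ribosome biogenesis genes had a median of 0.25 (27 measured, 19 above 0, percentile 99.97). The member past 2-fold was the U3 small nucleolar RNA-binding gene Rrp9, at least 2.38-fold higher, and the RNA polymerase I subunit gene Polr1b was 1.49-fold higher. The bound of Rrp9 was 0.84 on the log2 scale with the stricter background level. Interferon-stimulated genes had a median of 0.22 (28 measured, 22 above 0, percentile 99.87), and the 27 members above background on both arrays lay within 2-fold. Among these the antiviral gene Ifit3 was 1.68-fold higher, Dhx58, a regulator of cytosolic RNA sensing, 1.61-fold and Ifit1 1.56-fold, while Oas2 had a log2 ratio of -0.39. The dynamin-like GTPase gene Mx1, at background on the control array, was at least 1.71-fold higher.

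Chemokine genes went both ways, with a median of 0.05 (23 measured, percentile 80.38), 3 at least 2-fold higher and 2 at least 2-fold lower. Beside Ccl12, the interferon-inducible T-cell attractants Cxcl9 and Cxcl10 were 2.83-fold and 2.15-fold higher. Beside Ccl24, the B-cell attractant Cxcl13 was 2.00-fold lower. Averaging all probe sets brought Cxcl9 to 0.84 and Cxcl13 to -0.66 on the log2 scale, and moved the list's median to 0.37 (percentile 100.00). Chemokine receptor genes had a median of -0.18 (9 measured, percentile 5.83), with the scavenging receptor gene Ackr3 2.11-fold higher, the complement receptor gene C5ar1 1.91-fold higher, and Ccr2, the receptor of Ccl2 and Ccl12, at least 1.73-fold lower. This list lay below the random range under 4 of the 10 alternatives. Inflammatory cytokine and mediator genes had a median of -0.17 (15 measured, percentile 4.21), which was 0.09 with the background level at the median of all values. The prostaglandin synthase gene Ptgs2 was 2.38-fold lower, Il1b 1.77-fold lower and Osm 1.64-fold lower, while Il6 was 1.57-fold higher. The CSF1 array signal of Ptgs2, 153 units, lay under the stricter background level of 184.42 units, where its fold was a lower bound under 2-fold. Complement genes had a median of 0.01 (10 measured, percentile 63.54, from -0.07 to 0.04 over the alternatives), with the complement inhibitor genes Cd55 1.94-fold lower (-0.32 ± 0.61 over 3 probe sets) and Serping1 1.67-fold higher, and Cfb 1.34-fold lower. Toll-like receptor genes and their adaptors had a median of -0.07 (22 measured, percentile 16.01), with Tlr9 1.91-fold higher and Tlr2 1.62-fold lower.

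Genes of alternative activation, the state that interleukin-4 induces in macrophages, had a median of -0.34 (14 measured, 10 below 0, percentile 0.02). Beside Chil3, the transglutaminase gene F13a1 was 2.26-fold lower, the transcription factor gene Irf4 at least 1.98-fold lower, and Socs2 1.83-fold lower. The arginase gene Arg1, at 38212 units on the control array and 30700 units on the CSF1 array, had a log2 ratio of -0.32. Its signals lay close to the highest on the arrays, 46452 and 39157 units, where saturation was not tested. Mrc1 had a log2 ratio of 0.16. Urokinase system and matrix protease genes had a median of -0.17 (18 measured, percentile 2.02), which lay inside the random range after quantile normalization, at -0.10 and percentile 5.81. In this list thrombospondin Thbs1 was 2.16-fold lower, with a mean log2 ratio of -1.11 ± 0.01 over 2 probe sets, and the collagenase gene Mmp8 2.10-fold lower. The gelatinase gene Mmp2 was 2.07-fold higher on its brightest probe set and 1.62-fold on its other one.

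MHC class II genes had a median of -0.18 (12 measured, 11 below 0, percentile 3.74), with the costimulatory gene Cd86 1.68-fold lower. Their median lay below the random range under 6 of the 10 alternatives. MHC class I genes had a median of -0.11 (14 measured, percentile 14.18), with B2m at -0.28. Scavenger receptor, Fc receptor and phagocytosis genes had a median of -0.11 (24 measured, percentile 7.79), with the receptor gene Mertk 1.68-fold lower and the scavenger receptor gene Marco 1.64-fold higher. Gas6, which bridges apoptotic cells to their receptors, was 1.86-fold higher on its 1 probe set above background on both arrays. With all probe sets averaged, Gas6 was at -0.30. Lysosomal genes had a median of -0.12 (25 measured, percentile 15.55), with Psap at -0.28. Actin, integrin and adhesion genes had a median of -0.07 as deposited and 0.03 after quantile normalization (30 measured, percentile 24.32), with Vcam1 1.48-fold higher, at 0.34 ± 0.37 over 3 probe sets.

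Among the remaining gene lists, all inside the random range with the values as deposited, single genes stood out more than their lists. Growth factor genes had a median of -0.12 (15 measured, percentile 13.11), and beside Vegfa the related Vegfc was 1.86-fold lower and Vegfb 2.21-fold higher. The control signal of Vegfb, 158 units, lay under the stricter background level of 184.42 units, where its fold was a lower bound under 2-fold. Apoptosis regulators had a median of -0.05 (20 measured, percentile 23.88), with the inhibitor of apoptosis Birc3 2.26-fold lower and the survival gene Bcl2l1 1.56-fold higher. Osteoclast differentiation genes had a median of -0.15 (17 measured, percentile 3.44), with the transcription factor genes Jdp2 1.86-fold higher and Nfatc1 1.42-fold lower (-0.17 ± 0.29 over 5 probe sets) and the RANK gene Tnfrsf11a 1.65-fold higher on its brightest probe set and 1.10-fold on its other one. This list lay below the random range under 4 of the 10 alternatives. Macrophage and myeloid transcription factors had a median of -0.07 (24 measured, percentile 11.32), with Tfe3 1.60-fold higher and Tfec 1.50-fold lower. Cebpd was 1.84-fold higher on its 1 probe set above background on both arrays and at -1.08 with all probe sets averaged. Unfolded protein response and amino acid stress genes had a median of -0.05 (25 measured, percentile 21.81), with the mTOR inhibitor gene Ddit4 at least 1.78-fold lower and the serine synthesis genes Phgdh and Psat1 1.78-fold and 1.58-fold higher. Oxidative stress genes and metallothioneins had a median of 0.06 (19 measured, percentile 91.59), with Nqo1 1.42-fold lower. The p53 targets had a median of 0.12 (15 measured, percentile 86.17), with Polk 1.43-fold lower.

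**Figure D3:**
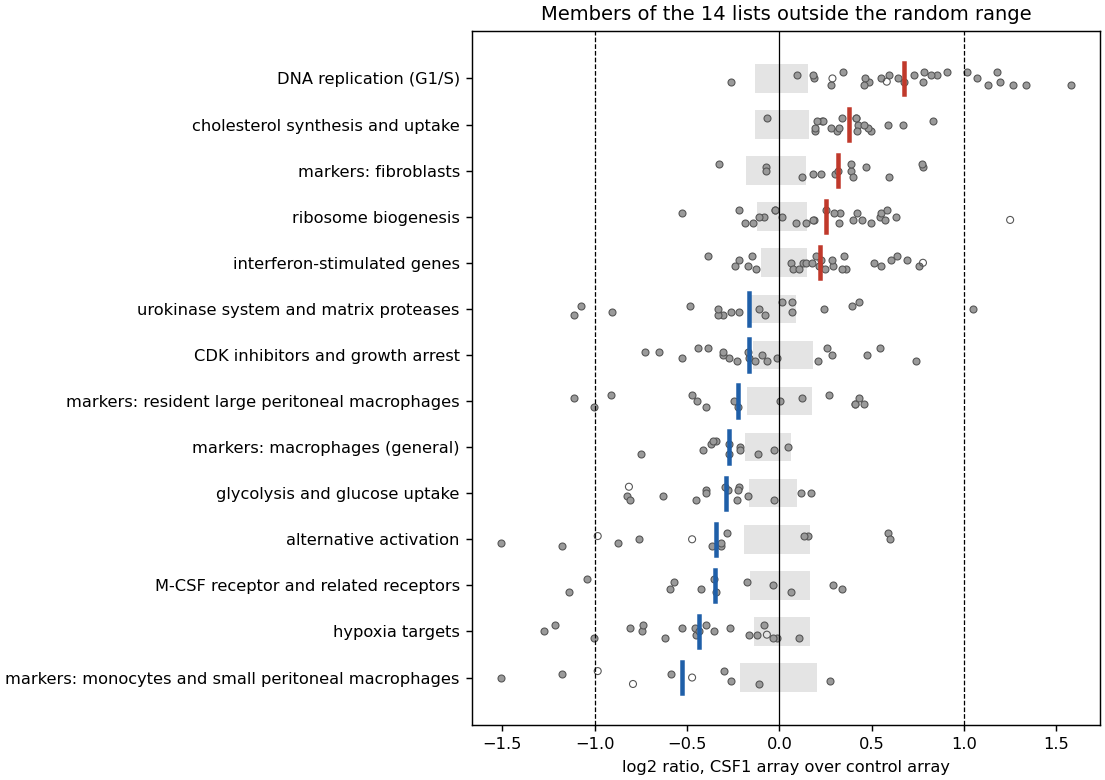
Log2 ratio of the CSF1 array over the control array for each measured member of the 14 lists whose median lay outside the central 95% of matched random lists, 1 point per gene, with open points for bounds. Coloured bars are list medians, from 0.67 for DNA replication to -0.53 for markers of monocytes and small peritoneal macrophages, grey bands are the central 95% of random list medians, and dashed lines mark 2-fold.

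Marker genes of the cell types that lavage fluid can hold were measured in the same way. General macrophage markers were very bright and mostly slightly lower, with a median of -0.27 (12 measured, 11 below 0, percentile 0.02). Cd68 stood at 38569 units on the control array and 28929 units on the CSF1 array, and Lyz2 was 1.29-fold lower, both close to the highest signals on the arrays. The median was -0.10 after quantile normalization (percentile 4.70), and the brightest 5% of all probe sets measured on both arrays had a median of -0.11. Markers of monocytes and small peritoneal macrophages had a median of -0.53 (10 measured, 9 below 0, percentile 0.00), led by Chil3, F13a1, Irf4 and Ccr2, of which the first 3 are also members of the alternative activation list. For 3 of the 10 the ratio is a bound, and without genes at background on either array the median was -0.31 (percentile 0.61). Markers of resident large peritoneal macrophages had a median of -0.22 (15 measured, 7 above 0 and 8 below, percentile 0.75). Thbs1, Cxcl13 and the lubricin gene Prg4 (1.88-fold) were lower and the transcription factor gene Gata6 was at -0.22, while the complement receptor gene Vsig4 was highest, at 0.46. That median was -0.07 after quantile normalization (percentile 21.69) and 0.01 with no background level.

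Fibroblast markers were higher as a group, beside the higher matrix genes Efemp1, Mgp and Mmp2. Of 15 measured, 12 were above 0 and none was past 2-fold, with a median of 0.32, or 1.25-fold (percentile 99.99). The PDGF receptor gene Pdgfrb was 1.71-fold higher, Loxl1 1.71-fold, decorin Dcn 1.51-fold and Sparc 1.39-fold. The collagen gene Col1a2 stood at 18991 units on the control array and 22188 units on the CSF1 array. Mesothelial markers had a median of 0.04 (7 measured, percentile 60.65), and those of endothelial cells had one of -0.33 (6 measured, percentile 6.68), which ranged from -0.60 to 0.23 over the alternatives. Lymphocyte lists lay inside the random range as deposited, with a median of 0.17 for B cells (8 measured, percentile 92.24, from -0.05 to 0.50 over the alternatives) and -0.06 for T cells and natural killer cells (12 measured, percentile 32.37). Within the latter list Gzma, Klrd1 (1.76-fold) and Prf1 (1.75-fold) were lower, while the T-cell receptor gene Cd3g had a log2 ratio of -0.04. Neutrophil markers had a median of -0.14 (6 measured, percentile 14.44), with Mmp8 and Csf3r lower and S100a8 at 0.18, and their median ranged from -0.75 to 0.19 over the alternatives. Dendritic cell markers had a median of -0.15 (5 measured, percentile 21.82). Among them the transcription factor gene Zbtb46 was 2.20-fold lower on its 1 probe set above background on both arrays and at -0.06 with all probe sets averaged. Its CSF1 array signal, 144 units, lay under the stricter background level of 184.42 units, where its fold was a lower bound under 2-fold. Mast cell markers had a median of -0.13 (6 measured, percentile 23.23). Only 2 markers each were measured for eosinophils, with Siglecf at -0.21 and Rnase2a at -0.13, and for erythroid cells and platelets, with Pf4 at -0.24 and Itga2b at 0.09.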

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

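The tests of a larger share of fibroblasts, of few genes deciding the hypoxia list and of single probe sets of Igfbp3, Efemp1 and Mgp were chosen after the results were seen, those of level-dependent scaling and of the other probe sets of replication genes before.

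Probe sets with no single gene name lie outside the gene comparison. Of 2157 measured, 14 were at least 2-fold higher on the CSF1 array and 29 at least 2-fold lower, with extremes of 3.62-fold higher and 3.06-fold lower. No gene can be named for them from the symbols used here.

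Fibroblast markers and the secreted matrix genes Igfbp3, Efemp1 and Mgp were higher on the CSF1 array, and level-dependent scaling as the cause is argued against by the median of the markers, which was 0.346 after the loess correction, with an SD of random list medians of 0.0779. The other probe set of Igfbp3 had a log2 ratio of 2.380, which argues against error of single probe sets there, while 0 other probe sets were measured for Efemp1 and Mgp, so it stays open for them. For the markers, a larger share of fibroblasts in the treated sample cannot be told apart from higher expression, since their SD of 0.306 was near the 0.29 between probe sets of a gene, with Col1a2 at 18991 and 22188 units and Col3a1 at 18382 and 24045 units on the control and CSF1 arrays. It stays open for the 3 matrix genes too: their lowest log2 ratio, 1.522, lies above the 0.78 of the highest of 15 markers, but they were picked for their large ratios. An effect of CSF1, a subset of stromal cells rich in these genes and a difference between samples stay open and untested.

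Hypoxia targets were lower on the CSF1 array. Level-dependent scaling is argued against by a median of -0.445 after the loess correction (SD of random list medians 0.0754). Without the 3 lowest, 17 of the 18 targets left lay below 0, where the central 95% of matched random lists reached at most 13. This argues against few genes deciding the list, but it follows from the 20 of 21 below 0 and is no separate test. Oxygen and cell density were not measured, so a difference between samples in either could account for the pattern as well as CSF1 could, and with 1 sample per group these are confounded.

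DNA replication genes were higher on the CSF1 array. Their median exceeded that of the fibroblast markers by 0.353 (SD of random list medians 0.0740). A rise as large as the marker median would fall short of this. However, the highest marker, at 0.78, lay above the replication median of 0.67, and the SD leaves out the markers' own spread. A larger share of fibroblasts therefore stays open. Error of single probe sets is argued against by a median of 0.708 over 22 other probe sets of 16 of these genes. Proliferation within macrophages may account for the pattern, as may proliferation within fibroblasts, and neither was tested. The treatment, the culture and the array are confounded here, and so may be the animals, since the labels do not say whether they were shared.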

How the results depend on the processing

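The restriction to genes above background on both arrays was chosen after seeing the data; all other alternatives were planned. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Of 429 list medians under the alternatives, 372 stayed within the spread of random list medians and 57 did not. Of the lists outside the random range, 1 changed sign, under 1 alternative; of those inside it, 9 did under at least 1 (early mitogenic response, cholesterol efflux, oxidative phosphorylation, inflammatory genes, complement, actin and adhesion, neutrophils, B cells and endothelial cells). Of 1891 values of named genes, taken relative to the median of all measured genes under the same alternative, 1778 stayed within the probe set spread and 113 moved by more. On that measure 10 named genes, none of them past 2-fold, had another sign under at least 1 alternative, in 0 cases a scaling. Centring on the median or the spikes shifts all genes alike, so it hardly acts on genes or lists measured this way. Of 59 named genes past 2-fold on that measure, 25 stayed past it under every alternative that recomputes a gene, 23 came under it in at least 1, and 19 had no value in at least 1. Not taken relative to the median, only 21 of the 79 lower genes stayed past 2-fold after centring on the spikes. Of the 14 lists outside the random range, 10 stayed outside on the same side under all 10 alternatives; cyclin-dependent kinase inhibitors, urokinase and matrix proteases, general macrophages and resident large peritoneal macrophages did not. Of the 29 lists inside it, 11 were outside under at least 1: MHC class II under 6, mitosis under 5, chemokine receptors and osteoclast differentiation under 4, chemokines, myeloid transcription factors and endothelial cells under 2, and the early mitogenic response, oxidative stress, B cells and neutrophils under 1. Signal over background limits genes near 139.26 units most. List medians and values of named genes are given relative to the median of all measured genes under the same alternative, and where no reason is given the cause was not tested. The counts of higher and lower genes that follow are not relative to that median.

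After quantile normalization, medians were -0.102 for general macrophages, -0.068 for resident large macrophages, -0.101 for urokinase and matrix proteases, -0.028 for lysosome, 0.016 for oxidative phosphorylation, 0.026 for actin and adhesion and 0.00 for cholesterol efflux. After the loess correction they were -0.167 for general macrophages, -0.094 for resident large macrophages, -0.046 for lysosome, -0.029 for efflux and -0.003 for oxidative phosphorylation. Centring on the spikes gave 341 genes higher and 21 lower, because it subtracts the spikes' mean log2 ratio of -0.29 from every gene, with medians of -0.270 for MHC class II and 0.001 for B cells.

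With the background level at the median of all values, which admits more genes, 195 genes were higher and 197 lower, and medians were -0.284 for MHC class II, 0.088 for inflammatory genes, -0.090 for endothelial cells and 0.097 for neutrophils. With the 95th percentile, 64 were higher and 52 lower, and medians were -0.291 for MHC class II, 0.204 for chemokines, -0.053 for inflammatory genes, -0.315 for mast cells, -0.350 for monocytes and small macrophages and 0.052 for neutrophils. With no background level, 1743 were higher and 1925 lower, and medians were -0.260 for the early mitogenic response, -0.104 for urokinase and matrix proteases, 0.501 for B cells, 0.226 for endothelial cells, 0.191 for neutrophils and 0.012 for resident large macrophages, the last 3 with another sign than as deposited. Only genes above background on both arrays gave -0.292 for MHC class II, 0.004 for efflux, -0.054 for inflammatory genes, -0.307 for monocytes and small macrophages and 0.174 for neutrophils.

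With the mean of all probe sets, 117 genes were higher and 130 lower, which kept 50 of the 105 higher and 41 of the 79 lower genes, and medians were 0.586 for DNA replication, -0.028 for MHC class I, -0.118 for actin and adhesion, 0.371 for chemokines, 0.016 for efflux, 0.286 for cholesterol synthesis, -0.356 for hypoxia targets, -0.142 for myeloid transcription factors, -0.300 for urokinase and matrix proteases and -0.046 for B cells. With probe sets not marked as shared, they were 0.745 for DNA replication, 0.307 for mitosis, -0.324 for MHC class II, -0.465 for alternative activation, -0.059 for cyclin-dependent kinase inhibitors, -0.039 for inflammatory genes, -0.169 for myeloid transcription factors, 0.151 for oxidative stress, 0.369 for ribosome biogenesis, -0.596 for endothelial cells, -0.748 for neutrophils and -0.102 for resident large macrophages, and mast cells had no median. In place of the genes at least 2-fold higher with CSF1, a threshold of 1.5-fold gave 650, and 3-fold gave 9; in place of the genes at least 2-fold lower with CSF1, they gave 594 and 6. With random lists not matched on level, mitosis (99.22) and endothelial cells (1.45) moved outside the random range and urokinase and matrix proteases (2.88) moved inside.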

Other observations

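The lists and genes in this part were chosen after the values were seen, and no explanation for them was tested. Leaving out the members with the most extreme ratios does not undo that choice, so the percentiles without them are descriptive only. Of 15 measured circadian clock and clock output genes, 12 were below 0, with a median log2 ratio of -0.34 (percentile 0.11), and without Per2, Dbp and Nfil3 the median was -0.23 (percentile 1.57). Of 15 measured cytotoxic lymphocyte genes, 14 were below 0, with a median of -0.60 (percentile 0.00). Without members among the 12 highest or lowest ratios or the largest bounds, the median was -0.49 (percentile 0.03). Gzmc was 2.19-fold lower.

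Of 30 measured secreted matrix and matricellular genes, 26 were above 0, with a median of 0.26 (percentile 100.00). Without members among the 12 highest or lowest ratios or the largest bounds, the median was 0.23 (percentile 99.98). Sfrp1, a secreted Wnt-binding protein, was 2.85-fold higher, with a mean log2 ratio of 1.48 ± 0.80 (SD between 3 probe sets), and the collagen gene Col11a1 was 2.59-fold higher. Arginine transport and metabolism genes had a median of -0.09 (percentile 14.25), which was 0.01 (percentile 49.02) without Arg2. The arginine transporter gene Slc7a2 was 2.51-fold lower and Ddah2, which breaks down methylated arginines, 2.55-fold higher. Npy, one of the background genes, stood at 5552 units on the control array and 10191 units on the CSF1 array, 1.84-fold higher.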
